A study of Mus musculus with 32 samples.

How the data were processed

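RNA from whole mouse liver was extracted with TRIzol and made into polyA libraries with the Tecan Universal Plus mRNA-seq with NuQuant kit, per the labels' protocols. The labels place 32 libraries in 4 groups of 8, from 2 genotypes (WT and FAAH S268D) and 2 diets (NASH and NASH-AA). Reads were processed with Trim Galore 0.6.7, UMI-tools 1.1.2 and STAR 2.7.10 against GRCm38, per the submitters' processing notes. The counting program, its annotation and its use of strand are not given in the sources used here. Without a stated strand, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies may have been divided between them.

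The authors deposited 1 table of estimated counts per gene, not scaled between libraries, with 55487 gene identifiers and symbols, and no column belonged to other samples (0). Many of the deposited counts were altered as text, as a spreadsheet does when it reads a decimal point as a digit-grouping or time mark. Of 1775584 cells, 87.9% were whole numbers and 11.4% carried digit-grouping marks on values with 3 decimals. In all, 52450 cells, those with more than 1 such mark included, did not read as a plain number. Digit-grouping marks, clock times and day fractions were turned back by fixed rules. For 1558 cells (0.088%) there were 2 possible originals, and the one closer to the gene's median over libraries, scaled for depth, was taken. In genes with a median of 5 or more, restored cells had median log2 ratios to the gene's median between -0.135 and 0.011, and whole numbers -0.004. The values were then rounded to whole numbers.

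Because the altered cells kept the table from being read as plain counts, its unit was recorded as other than counts. The planned edgeR quasi-likelihood test and its DESeq2 alternative were therefore not run. The test was instead limma-voom, which had been planned as an alternative, with limma 3.58.1 in R 4.3.3. Weights came from log2 CPM with a prior count of 0.5 and from TMM factors, computed by own code with 30% of log ratios and 5% of mean levels trimmed. Genes were kept with at least the CPM of 10 counts in a library of median size in 8 libraries and at least 15 counts in total, which left 14902 genes. One mean was fitted per group over all 32 libraries. There were 4 contrasts between 2 groups, the interaction and 2 averages, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Depth ran from 3851388 to 34370024 counts per library with a median of 22896437, and the second shallowest library held 14742982. Counting error is largest for genes of low counts and in the shallowest library, where 1 CPM stands for about 4 counts.

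Before the data were examined, 38 gene lists of pathways, liver cell types and cells that a liver piece could also hold were fixed, together with the groups, the contrasts and part of the alternatives. Of their 755 symbols 2 were not matched, and 37 lists had at least 3 members tested. Each was tested with camera at a preset correlation of 0.01, with the correlation estimated from the data, and with fry. With an estimated correlation, 0 lists passed in any of the 7 contrasts. The rule for the genes named was also fixed. It took Faah, and in each contrast the 6 higher and 6 lower genes with the largest absolute log2 fold change among those past the threshold, at a mean of at least 1 CPM. In a contrast of 2 groups, at least 6 of 8 libraries of each group had to lie on their own side of the other group's median. Predicted or unnamed genes and receptor segments were left out. From each list described, up to 4 members with the smallest unadjusted p were taken, whether or not they passed. Genes named outside this rule are said to be chosen after their values were seen.

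Gene positions are 1-based on GRCm38, from a GENCODE annotation in which 55141 of the 55487 identifiers were found, 53340 with the same symbol. Close copies were found by shared 31-base words of transcripts (at least 20% of a gene's words in another gene), and the coding gene closest to each of 527 processed pseudogenes by 21-base words. Alternatives were another normalization, no filter or a stricter one, blocks for the replicate number and the library number, a fold-change threshold, leaving out each library, fitting 2 groups alone, sample quality weights, limma-trend, each range of library numbers alone, leaving out genes near Faah or the 4 libraries numbered replicate 1, and the other reading of the cells with 2 possible originals. Those from sample quality weights onward were chosen after seeing the data. For each contrast the genes past the threshold were also counted in 100 splits of the libraries, the real one included.

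The fit was tested on simulated counts for 14902 genes, with means over all 32 libraries, the depth of each library and known changes in WT NASH-AA. It recovered 79 of 100 genes changed 2-fold and 94 of 100 changed 4-fold, with 11 false calls among 184 (6%), a rate slightly above the threshold. Camera called 0 of 36 unchanged lists. The simulated genes were drawn independently of each other, so this does not test camera on lists whose genes correlate. Each simulated gene had the same spread in all 4 groups, so the rate of false calls between groups of unequal spread was not tested. No libraries of a group were duplicates, since the lowest chi-square per gene between 2 libraries of a group was 16.3. Tables and figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.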

Results

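Whole-liver RNA was profiled in 32 libraries from mice of 2 genotypes and 2 diets. The mice were wild type (WT) or carried FAAH S268D, an amino acid substitution in fatty acid amide hydrolase, the enzyme that breaks down anandamide and other fatty acid amides, N-acyl taurines among them. The series text names 28 weeks on an HFFC diet with or without ARA, and the sample labels call the diets NASH and NASH-AA, the names used here. The title of the series concerns arachidonoyl-taurine, hepatic steatosis and inflammation. Each of the 4 groups held 8 libraries. Total counts averaged 23352195 ± 1424684 in WT NASH, 24305364 ± 4376941 in WT NASH-AA, 21460331 ± 7412370 in FAAH S268D NASH and 22650962 ± 5118692 in FAAH S268D NASH-AA (SD, n = 8 each). The shallowest library, FAAH S268D NASH replicate 1, held 3851388 counts, the next 14742982 and the deepest 34370024. Expression is given as normalised CPM (mean ± SD, n = 8 per group), and fold changes as log2 values ± SE. Adjusted p-values come from limma-voom over 14902 genes. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

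Faah itself (ENSMUSG00000034171, chromosome 4, 115967145 to 116017926, GRCm38) was measured at 154 ± 15.5 CPM in WT NASH, 156 ± 7.49 in WT NASH-AA, 186 ± 20.2 in FAAH S268D NASH and 180.1 ± 9.50 in FAAH S268D NASH-AA. Its mRNA was higher in FAAH S268D than in wild type on the NASH diet (log2 fold change 0.27 ± 0.06, adjusted p = 0.00677). On the NASH-AA diet the value was 0.21 ± 0.06 and did not pass (adjusted p = 0.104). Diet moved it by 0.03 ± 0.06 in wild type (adjusted p = 0.838) and -0.04 ± 0.06 in FAAH S268D (adjusted p = 0.835). A substitution need not alter the amount of transcript, so these values do not check the labels. Hepatocyte markers were also higher in FAAH S268D on the NASH diet (median log2 fold change 0.345). Genes around Faah were called for genotype at a higher rate than others. Whether the Faah difference comes from the substitution was not tested. The list of FAAH and N-acyl amide metabolism genes had 2 of 17 members higher on the NASH diet, 2 when adjusted over the list alone, Faah and Pm20d1, which makes N-acyl amino acids (Pm20d1 0.33 ± 0.09, adjusted p = 0.0197). As a set it did not pass camera on NASH (adjusted p = 0.145; adjusted p = 0.299 with an estimated correlation). On NASH-AA it did not pass either (adjusted p = 0.134; adjusted p = 0.401 with an estimated correlation), and 0 of 17 passed over all genes and 2 when adjusted over the list alone.

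The diet effect in wild type asked what the NASH-AA diet did relative to the NASH diet in livers with unaltered FAAH. Cyp2b9 and Cyp2b13, cytochrome genes of drug and steroid metabolism, rose. Cyp2b9 (chromosome 7, 26173411 to 26210661) went from 50.04 ± 30.9 to 175 ± 62.3 CPM (log2 fold change 2.14 ± 0.46, adjusted p = 0.0175), and Cyp2b13 from 4.90 ± 6.04 to 17.1 ± 7.98 CPM (2.57 ± 0.74, adjusted p = 0.044). These 2 genes are similar copies, so reads may have been split between them. Cfd, the complement factor D (adipsin) gene, rose from 9.23 ± 9.22 to 29.5 ± 16.8 CPM, and Dkk4, which encodes a Wnt antagonist, by 2.08 ± 0.59. Capn8 and Trhde also rose, by 1.62 ± 0.49 and 1.49 ± 0.38. Among the steepest falls were H19, an imprinted non-coding RNA (4.19 ± 2.54 to 0.68 ± 0.30 CPM), Cdh1, which encodes E-cadherin (29.6 ± 14.2 to 7.47 ± 2.90 CPM), and Aqp7, which encodes a glycerol channel (2.08 ± 1.37 to 0.31 ± 0.30 CPM). Cib3 fell by 3.10, Shc2 by 2.65 and Ephb2, a receptor tyrosine kinase gene, by 2.37 on the log2 scale.

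In all, 657 genes passed in wild type, 215 higher and 442 lower on NASH-AA. Of the 23 xenobiotic cytochromes tested, 7 rose and 1 fell over all genes, and 12 rose and 2 fell adjusted over the list alone, Cyp1a2 (0.93 ± 0.21), Cyp2a5 (0.88 ± 0.21) and Cyp2c29 (1.16 ± 0.28) among them. Camera gave the list adjusted p = 1.57e-05 (adjusted p = 0.355 with an estimated correlation). Hepatocyte markers had 4 of 20 higher and 1 lower, 11 higher and 1 lower adjusted over the list alone, with Ttr, the transthyretin gene, higher by 0.45 ± 0.10 and Cyp3a11 lower at -0.72 ± 0.20. Their camera result passed (adjusted p = 5.54e-07; adjusted p = 0.355 with an estimated correlation). Acute-phase proteins had 3 of 23 higher, Saa4, Itih4 and Saa3, and 7 adjusted over the list alone (camera adjusted p = 0.000367; adjusted p = 0.507 with an estimated correlation).

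Markers of monocytes and lipid-associated macrophages had 3 of 24 lower in wild type on NASH-AA over all genes, Itgam (-0.97 ± 0.27), Cd14 (-0.91 ± 0.26) and Cd9 (-0.63 ± 0.19), and 21 lower adjusted over the list alone. Camera gave adjusted p = 3.7e-10 (adjusted p = 0.355 with an estimated correlation). Dendritic cell and antigen presentation genes had 3 of 16 lower, 11 adjusted over the list alone, led by Clec9a (-0.44 ± 0.12), Cd209a and Batf3 (camera adjusted p = 5.17e-06; adjusted p = 0.355 with an estimated correlation). Cytokines, chemokines and adhesion genes had 5 of 25 lower, 8 adjusted over the list alone, with Il1a (-0.59 ± 0.13), Cxcl16 (-0.64 ± 0.15), Tgfb1 (-0.51 ± 0.13) and Ccl3 (-0.95 ± 0.27) among them. The set passed camera (adjusted p = 5.92e-06; adjusted p = 0.355 with an estimated correlation). Cholangiocyte and ductular markers had 4 of 15 lower, Tspan8, Sox4, Krt18 and Cldn4, and 7 adjusted over the list alone (camera adjusted p = 1.04e-05; adjusted p = 0.355 with an estimated correlation). Oncofetal and tumour-associated genes had 3 of 16 lower, H19, Akr1b8 and Scd2, and 6 adjusted over the list alone (camera adjusted p = 1.57e-05; adjusted p = 0.355 with an estimated correlation). In polyunsaturated fatty acid synthesis and remodelling, Lpcat1, a lysophospholipid acyltransferase gene, was the 1 gene of 13 lower (-0.72 ± 0.16), with 4 adjusted over the list alone (camera adjusted p = 0.00106; adjusted p = 0.355 with an estimated correlation). Some other non-hepatocyte lists leaned the same way and some did not. Genes of stellate cell activation and extracellular matrix had 33 of 34 members negative, 1 lower over all genes, Mmp14, and 0 adjusted over the list alone (camera adjusted p = 6.52e-06; adjusted p = 0.527 with an estimated correlation). Sinusoidal endothelial markers had 16 of 18 negative, 2 lower over all genes, Flt4 and Stab1, and 4 adjusted over the list alone (camera adjusted p = 0.00056; adjusted p = 0.507 with an estimated correlation). B and plasma cell markers had 7 of 12 positive (0 over all genes, 1 lower adjusted over the list alone; camera adjusted p = 0.681; adjusted p = 0.938 with an estimated correlation). Erythroid genes had 6 of 6 positive (0 over all genes, 1 higher adjusted over the list alone; camera adjusted p = 0.171; adjusted p = 0.639 with an estimated correlation). The count for the diet effect in wild type depended on the blocks and the libraries used. It was 370 genes under a block for the library number and 17 under a block for the replicate number. It was 0 among library numbers 1 to 16 alone and 164 among numbers 17 to 32. Leaving out single libraries, it lay between 64, without WT NASH replicate 2 or without WT NASH-AA replicate 5, and 2199, without WT NASH replicate 5, and 12 of the 32 libraries moved it by over 1.5 times when left out.

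The diet effect in FAAH S268D asked the same question in mutant livers. Apoa4, which encodes an apolipoprotein of triglyceride-rich particles, fell from 3032 ± 1660.0 to 526 ± 179 CPM (log2 fold change -2.30 ± 0.36, adjusted p = 0.00547). Apoa1, its neighbour on chromosome 9 and the gene of the main protein of high-density lipoprotein, fell from 5897 ± 949 to 4266 ± 576 CPM (-0.48 ± 0.09, adjusted p = 0.0279). Mvk, the mevalonate kinase gene of sterol synthesis, fell from 10.5 ± 1.02 to 7.43 ± 0.88 CPM. As3mt, an arsenite methyltransferase gene, fell by 0.79 on the log2 scale (SE 0.145, adjusted p = 0.0168) and Tnfaip8l1 fell by 0.61. Mup20, one of the major urinary protein genes, fell by 0.98, with reads that similar copies could share. Gypc, which encodes a glycophorin, rose from 9.29 ± 1.47 to 14.8 ± 2.55 CPM (0.64 ± 0.12, adjusted p = 0.0244).

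Here 14 genes passed, 4 higher and 10 lower. Of the genes of cholesterol synthesis and uptake, 1 of 24, Mvk, passed over all genes and 18 were lower adjusted over the list alone. Squalene epoxidase (Sqle) stood at 2.09 ± 1.80 CPM on NASH and 0.39 ± 0.35 on NASH-AA without passing over all genes (adjusted p = 0.18), and the Dhcr7 value was -0.77 ± 0.23. The list gave camera adjusted p = 5.19e-15 (adjusted p = 0.371 with an estimated correlation). FAAH S268D NASH replicate 3 stood apart on this list, with a mean of -0.90 log2 relative to all 32 libraries. The other libraries of its group lay between -0.07 and 0.83. This library was also the lowest of its group on other lipid lists. It scored -1.144 for fatty acid synthesis (others -0.28 to 0.909) and -0.895 for polyunsaturated fatty acid synthesis (others -0.065 to 0.447). For lipid droplet genes it scored -0.987 (others -0.224 to 0.381) and for PPARalpha targets -0.821 (others -0.204 to 0.529). Of polyunsaturated fatty acid synthesis and remodelling, 0 of 13 passed over all genes and 7 were lower adjusted over the list alone. The desaturase genes Fads1 and Fads2 gave -1.29 ± 0.39 and -1.14 ± 0.30 (camera adjusted p = 1.42e-06; adjusted p = 0.2 with an estimated correlation). Xenobiotic cytochromes had 0 of 23 past the threshold over all genes and 12 higher adjusted over the list alone, Cyp2a5 (0.87 ± 0.21), Cyp2c50 and Cyp2c37 among those with the smallest p. This set passed camera (adjusted p = 2.5e-11; adjusted p = 0.2 with an estimated correlation). Hepatocyte markers were positive in 18 of 20 members (camera adjusted p = 0.000202, and 0.649 with an estimated correlation). Cholangiocyte and ductular markers were negative in 13 of 15 (camera adjusted p = 4.73e-05, and 0.551 with an estimated correlation). Cell division genes were negative in 21 of 22 (camera adjusted p = 0.000333, and 0.649 with an estimated correlation). Lipid droplet and triglyceride storage genes had 0 of 24 over all genes, and 1 higher and 4 lower adjusted over the list alone, with Plin2, a lipid droplet coat protein gene, at -0.68 ± 0.19 and Dgat2, which makes triglyceride, at 0.36 ± 0.09. Camera gave the list a pass (adjusted p = 0.00466; adjusted p = 0.649 with an estimated correlation). Fatty acid synthesis genes had 0 of 18 on both scales, over all genes and adjusted over the list alone, with Fasn at -1.31 ± 0.53 (camera adjusted p = 0.000818; adjusted p = 0.649 with an estimated correlation).

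For the diet effect in FAAH S268D, monocyte and lipid-associated macrophage markers had 0 of 24 past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00022; adjusted p = 0.726 with an estimated correlation). Their mean log2 change was 0.18 among libraries numbered 1 to 16 and -1.03 among those numbered 17 to 32. Over all genes, the diet effects in the 2 genotypes correlated with Pearson's r = 0.546 across genes, which are not independent replicates. Of the 4 genes higher in FAAH S268D, 2 were also higher in wild type (0.06 for independent lists), with 0 of the 10 lower ones lower in wild type (0.3 for independent lists). The shared genes, chosen after their values were seen, were the unnamed Gm35696 (1.34 in FAAH S268D and 1.32 in wild type) and Gm11844 (0.90 and 0.58). The count of 14 ranged from 6, without FAAH S268D NASH-AA replicate 1 or replicate 4, to 361, without FAAH S268D NASH replicate 3, and 10 of the 32 libraries moved it by over 1.5 times.

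The genotype effect on NASH diet asked how FAAH S268D livers differed from wild type on the same food. Markers of macrophages and dendritic cells and a chemokine gene were lower in the mutant. Ccl3, a chemokine gene, was at 1.33 ± 0.47 CPM in wild type and 0.30 ± 0.22 in FAAH S268D (log2 fold change -2.05 ± 0.34, adjusted p = 0.000491). Cd68, a macrophage lysosomal marker, was at 52.4 ± 15.99 and 25.9 ± 8.46 CPM (-1.05 ± 0.20, adjusted p = 0.0029). Clec9a, a marker of type 1 dendritic cells, was at 3.50 ± 0.64 and 2.06 ± 0.47 CPM (-0.72 ± 0.13, adjusted p = 0.001). Sdhb, a subunit gene of succinate dehydrogenase that lies within 40 Mb of Faah, was higher in the mutant (146 ± 16.2 and 226 ± 52.6 CPM, 0.62 ± 0.10, adjusted p = 0.000491).

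A total of 1368 genes passed on the NASH diet, 430 higher and 938 lower in FAAH S268D, in the fit over all 32 libraries. That fit takes 1 spread per gene for all groups. The SD of the monocyte list score was 0.604 in WT NASH, 0.299 in WT NASH-AA, 0.788 in FAAH S268D NASH and 0.452 in FAAH S268D NASH-AA. A shared spread may thus be too small for this contrast. The 16 libraries of the 2 groups fitted alone gave 67 genes, and list members were not counted in that fit. Monocyte and lipid-associated macrophage markers had 19 of 24 lower over all genes and 22 adjusted over the list alone, with Mpeg1 (-0.67 ± 0.13), Fcer1g (-0.88 ± 0.18) and Lyz2 (-1.03 ± 0.22) beside Cd68 and a median of -0.98. These markers passed camera (adjusted p = 4.56e-16; adjusted p = 0.296 with an estimated correlation). The libraries of FAAH S268D NASH were spread widely on this list, with mean scores of -1.22, -0.96 and -1.30 in replicates 2, 3 and 4 and -0.06 to 0.74 in the other 5. WT NASH replicate 5 scored -0.49 and the other 7 of its group 0.70 to 1.53. The first principal component also parted FAAH S268D NASH, with replicates 1 to 4 at -46.4 to -19.7 and replicates 5 to 8 at 9.5 to 41.6. Cytokines, chemokines and adhesion genes had 18 of 25 lower and 22 adjusted over the list alone, including Il1rn, the interleukin 1 receptor antagonist gene (-1.22 ± 0.23), Icam1 (-0.80 ± 0.15) and Casp1 (-0.68 ± 0.13). For them camera gave adjusted p = 4.56e-16 (adjusted p = 0.229 with an estimated correlation). Dendritic cell and antigen presentation genes had 10 of 16 lower and 12 adjusted over the list alone, such as Cd86 (-0.84 ± 0.18) and H2-DMa (-0.99 ± 0.25) (camera adjusted p = 1.28e-07; adjusted p = 0.296 with an estimated correlation). Interferon response genes had 8 of 24 lower and 16 adjusted over the list alone, led by Gbp2 (-1.08 ± 0.22), Zbp1 and Ifit2 (camera adjusted p = 3.63e-08; adjusted p = 0.296 with an estimated correlation). T and NK cell markers had 6 of 16 lower and 12 adjusted over the list alone, with Cd8a at -2.15 ± 0.53 and Trac at -1.01 ± 0.28 (camera adjusted p = 1.35e-06; adjusted p = 0.296 with an estimated correlation). Neutrophil markers had 2 of 5 lower, S100a9 and Csf3r, and 5 adjusted over the list alone (camera adjusted p = 0.00234; adjusted p = 0.296 with an estimated correlation), and Csf3r lies within 40 Mb of Faah. Kupffer cell markers had 5 of 15 lower and 7 adjusted over the list alone, Clec1b (-0.72 ± 0.15) and the complement genes C1qa, C1qb and C1qc among them (camera adjusted p = 0.000116; adjusted p = 0.296 with an estimated correlation). Of these 15 markers, 4 lie within 40 Mb of Faah, namely Id3, C1qa, C1qb and C1qc.

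Cell division genes had 9 of 22 lower on the NASH diet and 16 adjusted over the list alone, with Mki67 (-1.12 ± 0.32), Top2a (-0.95 ± 0.27) and Plk1 (-1.05 ± 0.30) among them. As a set they passed camera (adjusted p = 4.08e-07; adjusted p = 0.299 with an estimated correlation). Stellate cell activation and extracellular matrix genes had 4 of 34 lower, Vim, Timp1, Mmp14 and Mmp13, and 9 adjusted over the list alone (camera adjusted p = 4.08e-07; adjusted p = 0.413 with an estimated correlation). Genes of mitochondrial oxidative phosphorylation had 6 of 24 higher and 20 adjusted over the list alone, among them Ndufv1 (0.24 ± 0.06) and Uqcrc1 (0.22 ± 0.06) (camera adjusted p = 2.37e-11; adjusted p = 0.296 with an estimated correlation). Hepatocyte markers had 7 of 20 higher and 1 lower, and 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.49e-06; adjusted p = 0.296 with an estimated correlation). Cyp2f2 was at 823 ± 242 CPM in wild type and 1307 ± 225 in FAAH S268D, while Cyp3a11 was lower, at 3204 ± 768 and 1964 ± 722 CPM. Bile acid synthesis and transport genes had 3 of 26 higher, Slc27a5, Hsd3b7 and Amacr, and 5 adjusted over the list alone (camera adjusted p = 0.00141; adjusted p = 0.296 with an estimated correlation). Markers of sinusoidal endothelium had 0 of 18 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.665; adjusted p = 0.928 with an estimated correlation).

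**Figure D1:**
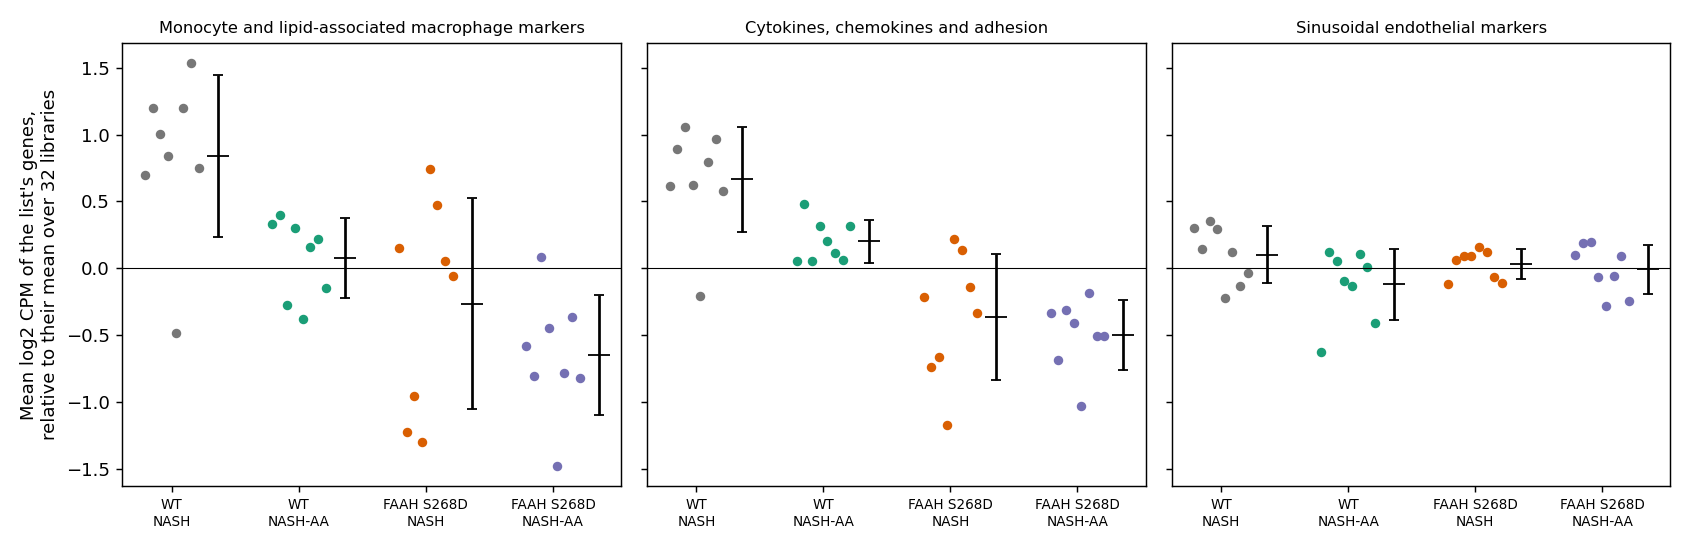
Each point is 1 library, placed by group on the x axis, and the y axis gives the mean log2 CPM of the genes of a list relative to their mean over the 32 libraries, with the group mean and SD (n = 8) beside the points. Monocyte and lipid-associated macrophage markers averaged 0.84 ± 0.60 in WT NASH, 0.08 ± 0.30 in WT NASH-AA, -0.27 ± 0.79 in FAAH S268D NASH and -0.65 ± 0.45 in FAAH S268D NASH-AA.

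Among the genes that the naming rule took, those with the largest fold changes on the NASH diet belonged to a few families and to chromosome 4. The rule leaves out pseudogenes, predicted genes and genes under 1 CPM, some of which changed more, such as Ndufs5-ps on chromosome 16 (5.42 ± 0.27, adjusted p = 2.75e-15). Mup7, Mup15, Mup1, Mup17, Mup9 and Mup2, which encode major urinary proteins, were higher in FAAH S268D by 1.97 to 3.52 on the log2 scale, with a wide spread (Mup7 254 ± 287 and 3603 ± 4814 CPM). These genes are near-identical copies clustered on chromosome 4, and how reads were divided between them is uncertain. The list of sex-biased liver genes, which holds Mup7, had 2 of 23 higher, Mup7 and Mup3, and 2 adjusted over the list alone (camera adjusted p = 0.0166; adjusted p = 0.347 with an estimated correlation). Its mean score was 0.68 to 0.84 in FAAH S268D NASH replicates 1 to 4 and -0.69 to -0.36 in replicates 5 to 8, against -1.45 to -0.07 in WT NASH. Serinc2 (chromosome 4, 130253495 to 130279205) was at 23.04 ± 4.81 CPM in wild type and 3.98 ± 2.59 in FAAH S268D (-2.83 ± 0.27, adjusted p = 2.43e-08). Tlr12 (chromosome 4, 128615443 to 128618619), a Toll-like receptor gene, was at 32.6 ± 5.79 and 4.86 ± 1.85 CPM (-2.74 ± 0.23, adjusted p = 1.79e-09). Fbxo44 (-2.65 ± 0.69), Zfp982 (-2.51 ± 0.66) and Zfp984 (-2.85 ± 0.59), also on chromosome 4, and Cib3 on chromosome 8 (-2.51 ± 0.69) were lower. Csad, which encodes cysteine sulfinic acid decarboxylase of taurine synthesis, was at 170 ± 35.8 CPM in wild type and 85.9 ± 25.7 in FAAH S268D (-1.003 ± 0.17, adjusted p = 0.000742). It was the 1 gene of 12 in the taurine and cysteine metabolism list that passed, over all genes and adjusted over the list alone. That list did not pass camera (adjusted p = 0.998; adjusted p = 0.999 with an estimated correlation). The genotype count on the NASH diet lay between 491, without FAAH S268D NASH replicate 4, and 2653, without WT NASH replicate 5, and 7 of the 32 libraries moved it by over 1.5 times. Fitting the 16 libraries of the 2 groups alone gave 67 genes.

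The genotype effect on NASH-AA diet took in fewer genes in the fit over all 32 libraries, an order that turned in some other fits. Most of the genes that the naming rule took lie on chromosome 4. Ndufs5-ps, a pseudogene on chromosome 16 outside the rule, changed more than they did (5.33 ± 0.27, adjusted p = 5.54e-15). Serinc2 was at 15.3 ± 3.26 CPM in wild type and 2.20 ± 1.19 in FAAH S268D (log2 fold change -2.89 ± 0.32, adjusted p = 4.68e-07). Tlr12 was at 23.6 ± 7.88 and 4.09 ± 0.86 CPM (-2.45 ± 0.24, adjusted p = 3.25e-08), and Sytl1 at 8.74 ± 1.36 and 2.89 ± 1.58 CPM (-1.72 ± 0.19). Il22ra1, an interleukin 22 receptor gene, and Ptpru, a receptor tyrosine phosphatase gene, fell by 1.69 and by 1.28. Extl1 (22.4 ± 4.09 and 41.5 ± 5.04 CPM) and Ttc39a (6.84 ± 2.77 and 14.6 ± 3.21 CPM) were higher. Ttc39aos1 was higher by 1.97 ± 0.23. Its annotated interval (109403794 to 109406155) does not overlap that of its neighbour Ttc39a (109406623 to 109444745). Whether the 2 changes are separate was not tested.

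Outside chromosome 4, Slco1a4, an organic anion transporter gene, rose from 17.3 ± 6.38 to 43.1 ± 16.7 CPM (1.29 ± 0.29, adjusted p = 0.0271), Setbp1 from 1.18 ± 0.21 to 2.92 ± 1.40 CPM, and Chic1 by 1.24 ± 0.29. Apoa4 fell from 1467 ± 604 to 526 ± 179 CPM (-1.47 ± 0.36, adjusted p = 0.0453). Csad fell from 160.5 ± 45.5 to 69.9 ± 13.8 CPM (-1.17 ± 0.17, adjusted p = 6.4e-05), 1 of 12 taurine and cysteine metabolism genes over all genes and 1 of 2 adjusted over the list alone (camera adjusted p = 0.517; adjusted p = 0.692 with an estimated correlation).

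On the NASH-AA diet, 98 genes passed for genotype, 52 higher and 46 lower. Monocyte and lipid-associated macrophage markers had 0 of 24 past the threshold over all genes and 14 lower adjusted over the list alone, with Fcer1g at -0.76 ± 0.19 and Cd68 at -0.70 ± 0.20. The markers as a set passed camera (adjusted p = 2.5e-11; adjusted p = 0.401 with an estimated correlation). Cytokines, chemokines and adhesion genes had 0 of 25 over all genes and 18 lower adjusted over the list alone, with Icam1 at -0.61 ± 0.15, Tlr2 at -0.85 ± 0.22 and Il1b at -1.10 ± 0.30. This list also passed camera (adjusted p = 1.75e-11; adjusted p = 0.401 with an estimated correlation). Cell division genes had 0 of 22 over all genes and 10 lower adjusted over the list alone (camera adjusted p = 1.99e-08; adjusted p = 0.401 with an estimated correlation). Interferon response genes had 0 of 24 over all genes and 3 lower adjusted over the list alone (camera adjusted p = 1.99e-08; adjusted p = 0.401 with an estimated correlation). NRF2 and oxidative stress genes had 0 of 22 over all genes and 4 lower adjusted over the list alone, with heme oxygenase 1 (Hmox1) at -0.62 ± 0.16 (camera adjusted p = 0.000441; adjusted p = 0.401 with an estimated correlation). Xenobiotic cytochromes had 0 of 23 over all genes and 6 higher adjusted over the list alone (camera adjusted p = 1.14e-05; adjusted p = 0.401 with an estimated correlation). Kupffer cell markers had 0 of 15 over all genes and 5 lower adjusted over the list alone (camera adjusted p = 0.000192; adjusted p = 0.401 with an estimated correlation). Hepatocyte markers had 0 of 20 over all genes and 0 adjusted over the list alone, with 18 positive (camera adjusted p = 0.000789; adjusted p = 0.445 with an estimated correlation). Sinusoidal endothelial markers had 0 of 18 over all genes and 0 adjusted over the list alone, with 15 positive (camera adjusted p = 0.0214; adjusted p = 0.569 with an estimated correlation). The genotype count on NASH-AA was 65 without FAAH S268D NASH-AA replicate 5 and 189 without WT NASH replicate 5, and 627 when the 16 libraries of the 2 groups were fitted alone. The order of the diets turned in that fit (67 on NASH) and among library numbers 17 to 32 (41 on NASH-AA and 20 on NASH).

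Genes around Faah on chromosome 4 were called for genotype at a higher rate than others. Within 40 Mb of Faah, a window chosen after the data were seen, 46 of 604 genes passed on NASH-AA (7.62%) and 52 of 14298 elsewhere (0.364%; 2-sided Fisher's exact test, p = 5.07e-38). On the NASH diet 118 of 604 genes passed there (19.5%) and 1250 of 14298 elsewhere (8.74%; Fisher's exact test, p = 1.05e-15). Genes are not independent replicates, so these p-values describe how the calls are placed. Calls for diet in wild type showed no such excess, with 24 of 604 genes (3.97%) and 633 of 14298 (4.43%; Fisher's exact test, p = 0.685). Genotype effects on the 2 diets correlated across genes with Pearson's r = 0.642, at 0.891 within 40 Mb of Faah and 0.613 elsewhere. Of the genes called on both diets, 31 were higher in both (1.5 for independent lists) and 31 lower in both (2.9 for independent lists). No library was used in both of these comparisons.

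**Figure D2:**
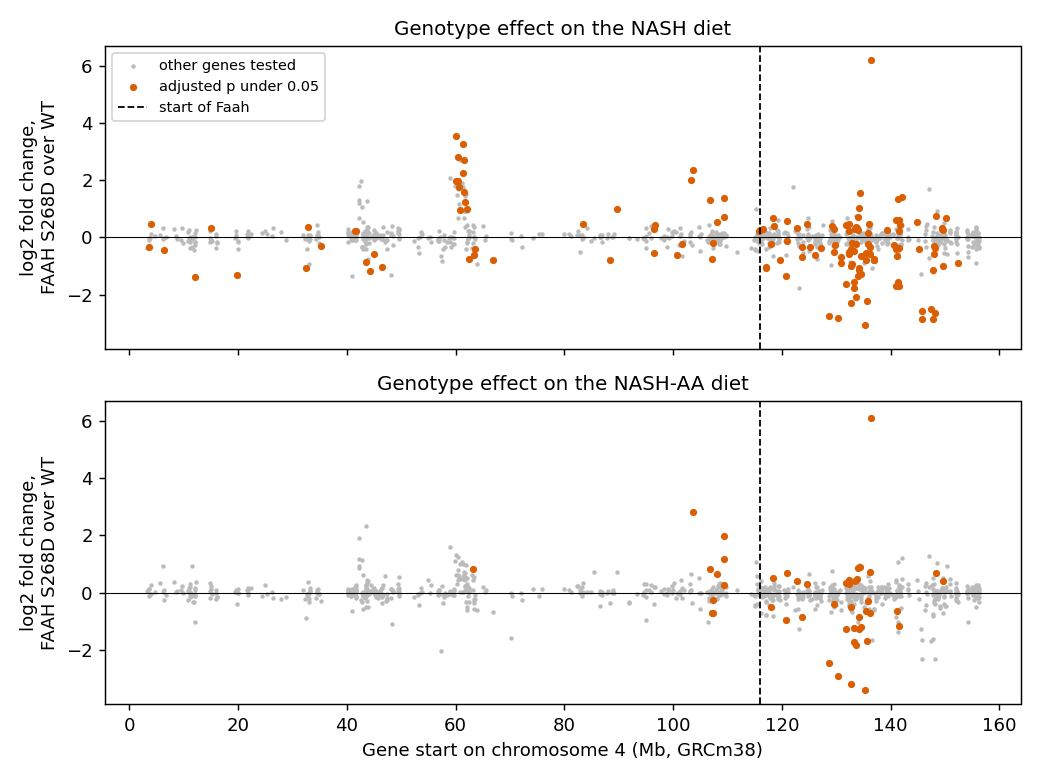
Each point is a gene tested on chromosome 4, by its start (x axis, Mb) and its log2 fold change of FAAH S268D over WT (y axis), with the NASH diet above and the NASH-AA diet below and the dashed line at the start of Faah. Genes with adjusted p under 0.05 are drawn in colour, and 46 of the 604 genes within 40 Mb of Faah passed on NASH-AA against 52 of 14298 elsewhere in the genome.

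Some processed pseudogenes on other chromosomes were higher in FAAH S268D, and these genes were chosen after their values were seen. Ndufs5-ps (chromosome 16, 42955631 to 42955949) rose on average over the diets by 5.37 on the log2 scale (adjusted p = 1.26e-19). The coding gene closest to it in sequence, Ndufs5 (chromosome 4, 123712710 to 123718202), a subunit gene of respiratory complex I, fell by 0.76 (adjusted p = 1.12e-09). Ndufs5 averaged 52.6 ± 5.82 CPM in the 16 wild-type libraries and 32.2 ± 7.46 in the 16 of FAAH S268D, and the sum of Ndufs5 and Ndufs5-ps 53.2 ± 5.84 and 53.3 ± 11.05 CPM. Hdac1-ps on chromosome 17 and Gm4864 on chromosome 12 rose by 2.22 and 4.52 (adjusted p = 1.35e-10 and 4.25e-16), while Hdac1, a histone deacetylase gene on chromosome 4, fell by 0.44 (adjusted p = 1.18e-07). Of the other pseudogenes that rose with a closest gene near Faah, Gm6594 (4.37) and Gm10182 (2.77) are closest to Hmgn2 (-0.05, adjusted p = 0.612) and Gm10036 to Rpl11 (-0.15, adjusted p = 0.103), neither of which passed. The sum of Hdac1, Hdac1-ps and Gm4864 was 20.7 ± 1.23 CPM in wild type and 17.7 ± 2.94 in FAAH S268D.

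**Figure D3:**
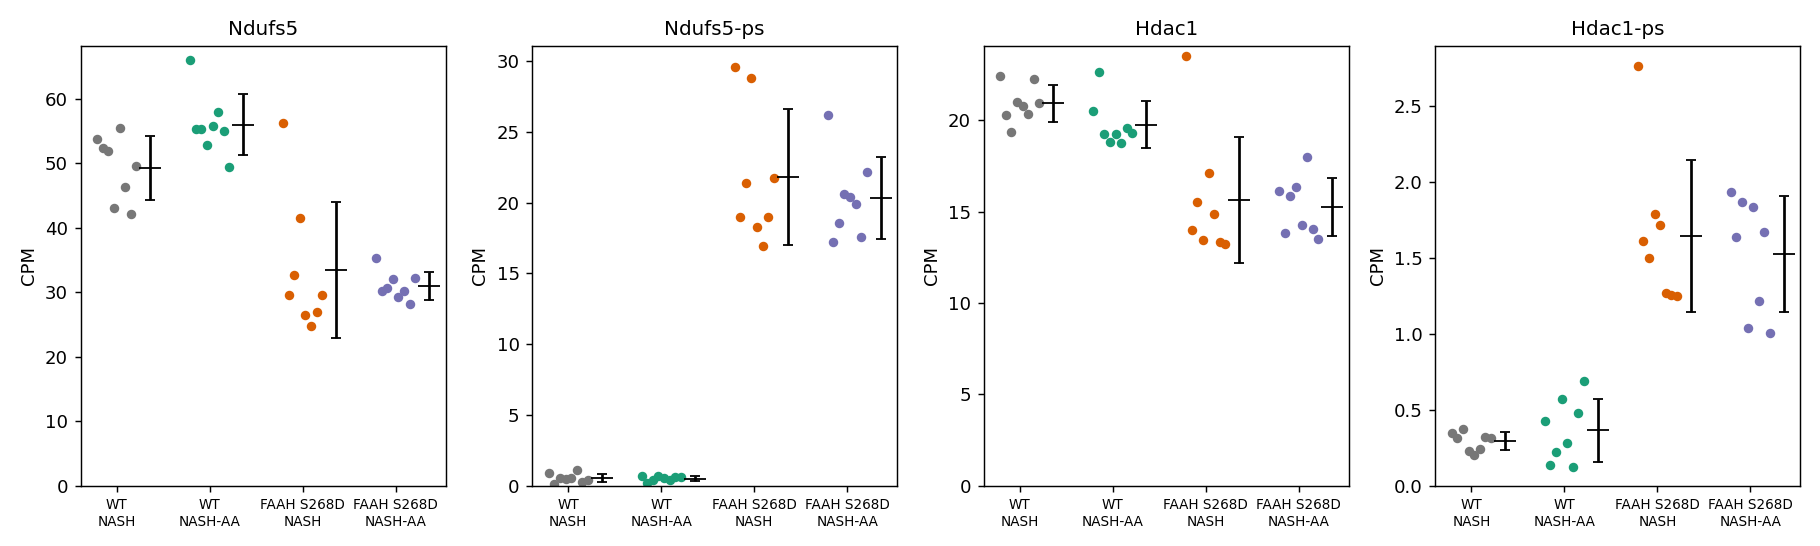
Each point is 1 library, placed by group on the x axis, and the y axis gives the CPM of a chromosome 4 gene or of a pseudogene close to it in sequence, with the group mean and SD (n = 8). Ndufs5-ps lay between 0.16 and 1.102 CPM in the WT libraries and between 16.96 and 29.6 in the FAAH S268D libraries.

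The interaction of genotype and diet asked whether the diet effect differed between genotypes. No single gene passed. Faah gave -0.06 ± 0.09 (adjusted p = 0.929), and Cyp3a11, Clec9a and Mvk gave 1.09 ± 0.28, 0.56 ± 0.18 and -0.52 ± 0.14, each with adjusted p = 0.906. Cholesterol synthesis and uptake genes leaned to a more negative diet effect in FAAH S268D in 24 of 24 members (median -0.51; 0 past the threshold over all genes and 1 adjusted over the list alone; camera adjusted p = 1.32e-10; adjusted p = 0.776 with an estimated correlation). Oxidative phosphorylation genes did so in 24 of 24 members (median -0.18; 0 over all genes and 0 adjusted over the list alone; camera adjusted p = 3.73e-10; adjusted p = 0.776 with an estimated correlation). Fatty acid synthesis genes did so in 16 of 18 (0 over all genes and 0 adjusted over the list alone; camera adjusted p = 3.89e-06; adjusted p = 0.776 with an estimated correlation). Monocyte and lipid-associated macrophage markers leaned the other way in 24 of 24 members (median 0.29; 0 over all genes and 0 adjusted over the list alone; camera adjusted p = 0.00291; adjusted p = 0.776 with an estimated correlation). Their mean was 0.95 among libraries numbered 1 to 16 and -0.31 among those numbered 17 to 32, so the direction turned, and that of oxidative phosphorylation genes was -0.33 and 0.01. In limma-voom 0 of 14902 genes passed, with 628 at an unadjusted p under 0.05 where 745 are due to chance, and limma-trend and limma-voom with sample quality weights also gave 0. So an effect that passed in one genotype or on one diet and not in the other was not shown to differ between them.

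Averaged over genotypes, the average diet effect took in 1624 genes, 689 higher and 935 lower on NASH-AA. Cyp2b13 (2.58 ± 0.50), Obp2a (2.33 ± 0.62), Cyp2b9 (1.85 ± 0.33), Cfd (1.85 ± 0.41), Hao2, a peroxisomal hydroxy acid oxidase gene (1.47 ± 0.37), and Cyp2c37 (1.33 ± 0.24) rose most among the genes that the naming rule took, which leaves out predicted genes and those under 1 CPM. Under the same rule Cib3, Shc2, Ephb2, Pls1, Insyn1 and Sdcbp2 fell by 2.82, 2.702, 2.66, 2.33, 2.31 and 2.22 on the log2 scale. Xenobiotic cytochromes had 12 of 23 higher and 14 adjusted over the list alone (camera adjusted p = 7.82e-09; adjusted p = 0.31 with an estimated correlation). Genes of polyunsaturated fatty acid synthesis and remodelling had 7 of 13 lower and 11 adjusted over the list alone (camera adjusted p = 6.89e-06; adjusted p = 0.31 with an estimated correlation). Monocyte and lipid-associated macrophage markers had 10 of 24 lower and 19 adjusted over the list alone (camera adjusted p = 7.82e-09; adjusted p = 0.418 with an estimated correlation). Hepatocyte markers had 8 of 20 higher and 14 adjusted over the list alone (camera adjusted p = 4.45e-07; adjusted p = 0.31 with an estimated correlation). Cholangiocyte and ductular markers had 7 of 15 lower and 10 adjusted over the list alone (camera adjusted p = 1.37e-06; adjusted p = 0.31 with an estimated correlation). Leaving out 1 library gave 996 genes without FAAH S268D NASH replicate 5 and 2717 without WT NASH replicate 5.

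The average genotype effect took in 2559 genes, 1028 higher and 1531 lower in FAAH S268D. Monocyte and lipid-associated macrophage markers had 21 of 24 lower and 23 adjusted over the list alone (camera adjusted p = 2.43e-16; adjusted p = 0.27 with an estimated correlation). Genes for cytokines, chemokines and adhesion had 21 of 25 lower and 21 adjusted over the list alone (camera adjusted p = 2.43e-16; adjusted p = 0.216 with an estimated correlation). Interferon response genes had 17 of 24 lower and 19 adjusted over the list alone (camera adjusted p = 4.92e-10; adjusted p = 0.27 with an estimated correlation). Among cell division genes, 14 of 22 were lower and 18 adjusted over the list alone (camera adjusted p = 3.54e-09; adjusted p = 0.27 with an estimated correlation). Hepatocyte markers had 11 of 20 higher and 14 adjusted over the list alone (camera adjusted p = 2.91e-06; adjusted p = 0.27 with an estimated correlation). The named genes with the largest changes were Mup7, Mup15, Mup1, Mup12, Eno1b and Ttc39aos1 on the higher side (1.67 to 2.43) and Serinc2, Tlr12, Fbxo44, Cib3, Zfp984 and Zfp982 on the lower side (-2.86 to -2.10). Eno1b is a near-identical copy of Eno1, a chromosome 4 gene, so its reads may be shared.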

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

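The tests of how genotype calls are placed along chromosome 4, of the sums of genes and their pseudogenes, of endothelial against monocyte markers, of the interaction within ranges of library numbers and of splits at an unadjusted p were chosen only after the result was seen, and the other tests here before their own result was seen.

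Genes within 40 Mb of Faah, such as Serinc2, Tlr12 and Extl1, were called for genotype at a higher rate than others on both diets, though most calls lay elsewhere (1250 of 1368 on NASH and 52 of 98 on NASH-AA). A response to the substitution spread evenly over the genome would need similar rates near Faah and elsewhere. On the NASH-AA diet the rate was 20.9-fold higher within 40 Mb, and on the NASH diet the rates were 19.5% and 8.74%. This excess is the pattern itself, in a window chosen after the data were seen, so it is no separate test. Reads shared between gene copies cannot account for it as a whole (24-fold without genes that have a close copy), nor can the order of library numbers (44 of the 46 genes near Faah passed with that block). Strain variants carried along with the mutated allele may contribute. Of 7 processed pseudogenes higher in FAAH S268D by 1 or more on the log2 scale, 6 had their closest coding gene within 40 Mb of Faah. Of the 465 others, 18 did (Fisher's exact test, p = 6.12e-08). Hdac1-ps and Gm4864 share the closest gene Hdac1, and Gm6594 and Gm10182 share Hmgn2. These pseudogenes are thus not independent, and the p-value is too small. The summed level of Ndufs5 and Ndufs5-ps moved by 0.004 on the log2 scale, as shared reads would give. That of Hdac1, Hdac1-ps and Gm4864 moved by -0.22, which shared reads alone do not give. Open remain true differences in transcript level caused by linked variants, reads that align differently to variant sequence, and an effect of the substitution on its neighbourhood, which was not tested.

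Monocyte, chemokine and antigen presentation genes, such as Cd68, Ccl3 and Cd86, were lower in FAAH S268D on the NASH diet, most so in its replicates 2, 3 and 4 (mean score of the monocyte list -1.22, -0.96 and -1.30, against -0.06 to 0.74 in its other 5 libraries). A lower share of all non-hepatocyte cells would lower endothelial markers alike, but monocyte markers averaged -1.11 ± 0.10 and sinusoidal endothelial markers -0.06 ± 0.04 (SE over members), a difference of -1.06. Members of a list correlate, so these SEs leave out the spread between libraries. Stellate cell and matrix genes were negative in 34 of 34 members (mean -0.51), while B and plasma cell markers were positive in 8 of 12. A lower share of some other non-hepatocyte cells thus stays open. The shallow library is argued against as the whole cause, since the monocyte mean was -1.13 without FAAH S268D NASH replicate 1. Within both ranges of library numbers the mean was -0.59 or lower, past the bound of -0.2 fixed for this test. Library numbers cut into these ranges are thus argued against as the whole cause. Genotype effects on NASH correlated across genes at 0.312 between the ranges, so their size may still depend on library number. The ranges do not part replicates 1 to 4 of FAAH S268D NASH from replicates 5 to 8, so that split was not tested. A hypothesis is that the genotype may go with fewer such cells or with less of these transcripts per cell, which whole-liver RNA cannot separate. Litter and cage are not in the labels, what sets those 3 libraries apart was not tested, variants linked to Faah stay possible, and with a correlation estimated from the data none of these lists passed.

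FAAH S268D NASH replicate 1 stood apart from its group, at 3851388 counts where the others held 21349261 to 26662507, and its ribosomal protein share was 1.85% against 1.16% to 1.35%. Low depth may account for part of its distance from the rest (0.897, root mean square log2), since thinning the other 7 libraries to that depth raised theirs from between 0.443 and 0.666 to between 0.572 and 0.73, which is 63.7% to 81.4% of it and leaves a gap. A GC content bias particular to this library is argued against, as the correlation of its deviation with GC (rho 0.152) lay inside the range of the other 31 libraries. The other 3 libraries numbered replicate 1 gave 0.164, 0.143 and 0.086, so a GC bias shared by these 4 libraries stays open. With transcript length, the correlation of FAAH S268D NASH replicate 1 (-0.527) lay outside the range of the other 31. The other 3 libraries numbered replicate 1 gave -0.444, -0.461 and -0.429, so a length bias shared by these 4 libraries is also open. No biological explanation was tested.

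Single libraries far from the rest of their group occurred in 12 of 212 groups tested, where chance gives about 10.6. Besides the depth and ribosomal protein share above, WT NASH-AA replicate 7 held 34370024 counts (others 20974679 to 26013813). Cyp2b13 was at 2.19 CPM in FAAH S268D NASH-AA replicate 5 (others 12.5 to 52.7), Trhde at 0.0712 CPM in WT NASH replicate 7 (others 0.475 to 1.69) and Hao2 at 0.510 CPM in WT NASH-AA replicate 7 (others 2.40 to 7.05). As3mt was at 27.5 CPM in WT NASH replicate 4 (others 32.7 to 37.5) and 18.9 CPM in FAAH S268D NASH replicate 3 (others 33.3 to 44.8). Tlr12 was at 5.94 CPM in FAAH S268D NASH-AA replicate 7 (others 3.12 to 4.23), Zfp982 at 2.68 CPM in WT NASH-AA replicate 2 (others 4.36 to 6.54) and Ttc39a at 6.18 CPM in WT NASH replicate 5 (others 10.6 to 14.6). Eno1b was at 16.1 CPM in FAAH S268D NASH replicate 8 (others 132 to 327).

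The diet effect differed between genotypes by camera for 15 lists, and for none of them with an estimated correlation (adjusted p = 0.776 in each). Toward a more negative diet effect in FAAH S268D leaned cholesterol synthesis and uptake (camera adjusted p = 1.32e-10), oxidative phosphorylation (3.73e-10), fatty acid synthesis (3.89e-06), hepatocyte markers, zonation genes and NRF2 genes (0.037 each), and lipid droplet and lipoprotein genes (0.0421 each). Toward a more positive one leaned dendritic cell genes (0.000987), monocyte markers (0.00291), cytokines and chemokines (0.00457), stellate cell and endothelial markers (0.00801 each), T and NK cell markers (0.0421) and muscle genes (0.0463). The interaction effects in libraries numbered 1 to 16 and 17 to 32 correlated across genes at -0.181. The mean turned sign between these ranges for monocyte (0.95 and -0.31), cytokine, stellate cell and endothelial genes, and also for T and NK cell markers, hepatocyte markers, zonation genes, NRF2 genes and oxidative phosphorylation, while cholesterol (-0.29 and -0.90) and fatty acid synthesis genes were negative in both.

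Other ways of splitting the libraries tested whether chance gives as many genes, over 100 splits for each contrast, the real one included. For the diet effect in wild type only 1 split, the real one, gave as many genes (657, highest other 82). The same held for genotype on NASH (1368, highest other 1261) and on NASH-AA (98, highest other 10). It also held for the average diet (1624, highest other 1) and genotype (2559, highest other 3) effects. Such counts were thus rare among random splits of libraries taken as independent. The splits cannot exclude a structure such as litter or cage. For diet in FAAH S268D (14 genes) 2 splits gave as many, the highest other 623 and 93 of the others 0. At an unadjusted p under 0.05, 6 splits gave as many genes as its 1845, so chance cannot be excluded for it. For the interaction the count of 0 genes tests nothing, since each of the 100 splits gives at least that (highest other 22), and at an unadjusted p under 0.05 41 splits gave as many as its 628, so chance cannot be excluded. How the splits with 623 and 1261 genes group the libraries was not examined, so a structure of the samples other than diet and genotype stays open there. The first principal component held 24.3% of the variance.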

How the results depend on the processing

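Sample quality weights, limma-trend, the ranges of library numbers, leaving out genes near Faah, leaving out the 4 libraries numbered replicate 1 and the other reading of the cells with 2 possible originals were chosen after seeing the data, and the other alternatives before. The planned edgeR test and its DESeq2 alternative were not run, since the unit of the altered table was recorded as other than counts. They were not tried on the restored, rounded values either. Median-of-ratios normalization, a stricter low-count filter and the other reading of those cells kept each count of genes within 1.5 times, both correlations within 0.1 and each Faah value on its side of the threshold. Lists were not tested under either change of filter, and the other 2 settings kept each count of lists within 1.5 times. Shallow libraries limit genes of low counts, and without a low-count filter the diet counts were 182 in wild type and 7 in FAAH S268D, and the correlations 0.217 (diet effects) and 0.405 (genotype effects); the cause was not tested.

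With the replicate number as a block, the counts were 17 and 8 for diet, 63 for genotype on NASH-AA and 1071 for average diet, and it moved no other count by over 1.5 times. Correlations over all genes showed no pairing by these numbers (13 of 48 same-number pairs over 0.1, and 5 of 32 libraries correlated best with their own number). They cannot exclude a structure that libraries of the same number share within a genotype. The 4 libraries numbered replicate 1 shared a trend with transcript length. Eno1b was high in replicates 2, 4 and 5 of both wild-type groups and low in the others. With the library-number block the diet effect in wild type gave 370 genes, 365 of them among the 657. Of 566 values of named genes, 88 no longer passed with the replicate block, 77 without a low-count filter, 65 without the 4 libraries numbered replicate 1, 41 in limma-trend and 37 with the library-number block, with 0 turned in these settings. Asking for an absolute log2 fold change of at least 1 left 89 and 2 genes for diet, 282 and 35 for genotype, 102 for average diet and 205 for average genotype, as fewer can pass.

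Fitting only the 16 libraries of the 2 groups gave 1092 and 3 genes for diet and 67 and 627 for genotype (NASH, then NASH-AA). Sample quality weights gave 3758 and 1063 for diet, 756 for genotype on NASH-AA, 5084 for average diet and 0.653 for the correlation of diet effects; Faah on NASH-AA then passed at 0.22 (adjusted p = 0.00393), and its average diet effect turned from -0.01 to 0.003. Limma-trend gave 247 and 41 for diet. Library numbers 1 to 16 alone gave 0 and 0 for diet and 883 and 17 for genotype, and numbers 17 to 32 gave 164, 372, 20 and 41; fewer libraries enter, and the rest of the cause was not tested. Without genes within 40 Mb of Faah, 52 passed for genotype on NASH-AA, and without the 4 libraries numbered replicate 1, 4 passed for diet in FAAH S268D.

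Of 37 lists tested, camera called 18 and 16 for diet, 20 and 19 for genotype, 15 for the interaction, 19 for average diet and 21 for average genotype; with an estimated correlation it called 0 in each. Fry called 9 and 2 for diet, 15 for genotype on NASH and 0 on NASH-AA. It called 0 for the interaction, 11 for average diet and 17 for average genotype.

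Leaving out 1 library at a time gave 64 to 2199 genes for diet in wild type, 6 to 361 for diet in FAAH S268D, 491 to 2653 and 65 to 189 for genotype, 0 to 0 for the interaction, 996 to 2717 for average diet and 1928 to 3323 for average genotype. The libraries that moved a count by over 1.5 times follow. Diet in wild type gave, without WT NASH replicates 2, 3, 4, 5, 7 and 8, 64, 248, 113, 2199, 111 and 227 genes, without WT NASH-AA replicates 3, 4, 5, 7 and 8, 278, 195, 64, 186 and 133, and without FAAH S268D NASH replicate 5, 1048. Diet in FAAH S268D gave, without FAAH S268D NASH replicates 2, 3 and 6, 53, 361 and 8, and without FAAH S268D NASH-AA replicates 1, 2, 3, 4, 6, 7 and 8, 6, 8, 50, 6, 7, 8 and 8. Genotype on NASH gave, without WT NASH replicates 2, 5 and 7, 837, 2653 and 726, and without FAAH S268D NASH replicates 2, 3, 4 and 5, 721, 791, 491 and 2605. Genotype on NASH-AA gave 189 without WT NASH replicate 5 and 65 without FAAH S268D NASH-AA replicate 5. Average diet gave 2717 without WT NASH replicate 5 and 996 without FAAH S268D NASH replicate 5.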

Other observations

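The values in this part were picked out after the data were seen, apart from the gene lists and their tests.

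Genes listed under eicosanoid synthesis, the making of prostaglandins, thromboxane, leukotrienes and epoxides from arachidonic acid, changed both ways with genotype on the NASH diet. Not every member of the list carries out such a step. Of 21 tested, 3 were higher and 6 lower in FAAH S268D over all genes, and 4 and 6 adjusted over the list alone. The lower ones included Pla2g4a, the cytosolic phospholipase A2 gene that releases arachidonic acid (-0.85 ± 0.20, adjusted p = 0.00792), Tbxas1, the thromboxane synthase gene (-1.03 ± 0.22, adjusted p = 0.00584), and Pla2g7 (-1.10 ± 0.21, adjusted p = 0.00283), while Cyp2j5, an epoxygenase gene within 40 Mb of Faah, was higher (0.45 ± 0.10, adjusted p = 0.00623). Monocyte and lipid-associated macrophage markers averaged -1.11 in the same contrast, and a link to the lower eicosanoid genes was not tested. The eicosanoid list as a whole did not pass camera (adjusted p = 0.459; adjusted p = 0.713 with an estimated correlation). On the NASH-AA diet 0 of 21 passed over all genes and 1 was lower adjusted over the list alone (camera adjusted p = 0.571; adjusted p = 0.692 with an estimated correlation).

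Genes of lipid storage and of fat burning moved little as groups on the NASH diet. FAAH S268D NASH replicate 3 was the lowest of its group on both lists (-0.987 and -0.821), which lowers these group means. Lipid droplet and triglyceride storage genes had 1 of 24 higher, Cideb (0.30 ± 0.08, adjusted p = 0.0206), and 1 lower, the lipoprotein lipase gene Lpl (-1.29 ± 0.30, adjusted p = 0.00874), with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.48; adjusted p = 0.84 with an estimated correlation). On NASH-AA 0 of 24 passed over all genes, and 1 was higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00134; adjusted p = 0.401 with an estimated correlation). PPARalpha targets and fatty acid oxidation genes had 1 of 30 higher on NASH, Acaa2 (0.26 ± 0.08, adjusted p = 0.0444), and 0 adjusted over the list alone (camera adjusted p = 0.296; adjusted p = 0.84 with an estimated correlation). Circadian clock genes had 0 of 20 past the threshold over all genes on NASH-AA and 4 higher adjusted over the list alone, with Tef at 0.40 ± 0.12 and Per3, which lies within 40 Mb of Faah, at 0.48 ± 0.15 (camera adjusted p = 0.00134; adjusted p = 0.401 with an estimated correlation).

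Eno1b, the near-identical copy of Eno1, took separate levels among wild-type libraries. It lay at 196, 164 and 160 CPM in WT NASH replicates 2, 4 and 5 and at 26.8, 41.9, 19.7, 12.3 and 21.9 CPM in replicates 1, 3, 6, 7 and 8. In WT NASH-AA it lay at 194, 172 and 168 CPM in replicates 2, 4 and 5 and at 30.5, 20.4, 22.9, 28.8 and 23.6 CPM in replicates 1, 3, 6, 7 and 8. The high levels thus fell on the same replicate numbers in both wild-type groups, and the cause was not tested. In FAAH S268D, Eno1b lay between 132 and 351 CPM, apart from 16.1 CPM in FAAH S268D NASH replicate 8.

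Among the 46 genes near Faah called for genotype on NASH-AA, FAAH S268D NASH-AA replicate 6 was the library of its group nearest to the wild-type mean for 18, and the other 7 libraries for 2 to 5 each. Cep85, 1 of these genes, was at 31.1 CPM in that library, between 14.5 and 17.9 CPM in the other 7 of its group, and between 32.4 and 58.8 CPM in the wild-type libraries. Htr1d, a serotonin receptor gene on chromosome 4, had counts in 1 of 16 wild-type libraries (WT NASH-AA replicate 5, 0.0949 CPM) and lay between 0.61 and 3.80 CPM in the 16 libraries of FAAH S268D.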
